A study of Homo sapiens with 12 samples.

How the data were processed

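Total RNA of SW620 cells was read on 12 Clariom S human arrays, 2 for each of 6 groups: CTRL, TIM-KD, ZEB1-KD and ZEB1/TIM-KDs at day 15 after infection, and CTRL and TIM-KD at day 60. Per the labels' protocols, cells were infected with lentivirus packaged in a 293T line, carrying pLKO.1 short hairpins against TIMELESS, against ZEB1 or a control construct, and were selected with puromycin. The treatment protocol names 2 hairpins per target and the study's design text 1 of them, and the labels of the arrays do not say which was used. If it was 1, a result cannot be told apart from an effect of that hairpin on other genes. The deposited values are log2 signals, per the submitters' processing notes made with RMA, a method that corrects background, quantile normalizes and summarizes per probe set, in the Transcriptome Analysis Console against hg38, whose versions are not given. All 12 value columns were used, with 21448 probe sets each, and the deposited values run from 2.31 to 18.24 with 2 decimals.

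Gene symbols and coordinates came from the probe annotation of the series, matched by gene identifier to a RefSeq table of the same assembly. Of the probe sets, 17709 carry 1 symbol (17687 distinct) and 3739 have no gene name here. Counts of calls are over all probe sets. The deposited values were not normalized again.

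Linear models were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 arrays, leaving 6 residual degrees of freedom. Variances were moderated with eBayes (prior degrees of freedom 5.69, prior SD 0.219 log2, median residual SD 0.229 log2). The median SE of a difference between 2 groups was 0.224 log2, and 0.317 for a difference of differences. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05, with the adjustment made over all 21448 probe sets within each comparison. Every adjusted p in the text is from limma. The 9 comparisons were fixed before the data were examined: each knockdown group against control at day 15, ZEB1/TIM-KDs against each single knockdown, the interaction of the knockdowns, TIM-KD against control at day 60, the difference of the TIM-KD effects of the 2 days, and the controls of day 60 against those of day 15.

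Gene lists were fixed at the same time: 24 lists with 676 genes, of which 606 were measured, and a list needed at least 8 measured genes. They cover fork protection and replication checkpoint, DNA replication, mitosis, sister chromatid cohesion, homologous recombination and Fanconi anaemia repair, p53 targets, senescence and secreted factors, the core clock, epithelial and mesenchymal genes, Wnt targets, colonocyte differentiation, MYC targets, ERK output, TGF-beta and YAP targets, NF-kB genes, interferon response, the unfolded protein and integrated stress response, hypoxia and glycolysis, cholesterol synthesis and oxidative phosphorylation. Markers of fibroblasts and endothelium, of leukocytes and of the packaging line were included to look for other cells. List shifts were tested with cameraPR of limma on the moderated t values with a preset correlation of 0.01, adjusted over the 24 lists of a comparison. The alternatives were camera with the correlation estimated from the residuals, and fry. List members were also tested with the adjustment made over the list alone.

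Genes named in the text follow a rule set before the data were examined. It takes TIMELESS and ZEB1, the 8 largest rises and 8 largest falls of each comparison (4 each for interactions and for time in the controls) among called probe sets with 1 symbol whose group values do not overlap, and up to 4 members with the smallest adjusted p from each list that passed or had at least 3 called members. Agreement between comparisons used those that share no array, with Pearson and Spearman correlations over all probe sets. For comparisons with shared controls, 100 simulated data sets with no effect gave the correlation that sharing alone produces.

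The fit was tested on simulated data with the fitted variances and 200 changed probe sets. For TIM-KD against control at day 15 it called 1.49% of the probe sets changed by 0.5 log2, 46.3% of those changed by 1 and 100% of those changed by 2, with 5 false calls among 103. For the interaction the shares were 0%, 2.99% and 77.3%, with 0 false calls among 53. The first form of this test asked for more than 90% of the largest changes in both comparisons, which the interaction did not reach. A list raised by 0.5 log2 was found, and 0 of the 23 other lists were called. The simulated noise was independent between genes, so this does not show how the list test behaves when genes of a list are correlated.

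Alternatives to the fit were the replicate number as a block, over all arrays or within a time point, fewer arrays in the fit, an intensity trend with a robust prior, array weights, quantile normalization, centring each array on its median, and leaving out probe sets with a mean under the 30th percentile (4.78, which keeps 15016). Where a gene's mean in 1 group lies under this limit, its signal is not shown to be above background, and the fold change is given as a lower bound. Others were 1 probe set per gene, fold thresholds of 1.5 and 2, an unadjusted threshold, and leaving out each array in turn. After the data were seen, 3 more were added: a block with the replicate numbers of TIM-KD at day 15 crossed, chromosomes 2, 5, 7, 10 and 20 left out, and quantile normalization for the lists. Medians by chromosome used genes with a mean of at least 8, in windows of 10 Mb, and were also chosen after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Raw intensity files and any other assays of the study were not analysed here.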

Results

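The series asks how gene expression in a colon cancer cell line changes when TIMELESS, ZEB1 or both are knocked down, and how the TIMELESS effect looks after a longer time in culture. TIMELESS (TIM) is a replication fork protein that works with TIPIN and CLSPN and has also been studied in the circadian clock. ZEB1 is a zinc finger transcription factor known to repress CDH1 and other epithelial genes. SW620 cells, a line from a lymph node metastasis, received lentiviral short hairpins, and RNA was read on 12 arrays, 2 per group. At day 15 after infection the groups were CTRL, TIM-KD, ZEB1-KD and ZEB1/TIM-KDs, and at day 60 they were CTRL and TIM-KD. Array medians lay between 6.2 and 6.42 on the log2 scale, and the Pearson correlation between the 2 replicates of a group was 0.990 to 0.996. On the first principal component, which held 45.5% of the variance, the day 60 arrays stood apart from the day 15 arrays. The replicates of ZEB1/TIM-KDs differed most, with an SD of their differences of 0.465 log2. On components 2 and 3 its replicate 2 lay nearer to the ZEB1-KD arrays than to its replicate 1. The replicates are called biological replicates in the study's design text, but the labels do not say that they were separate cultures or infections. The p-values therefore measure the spread between these samples, which may be technical. With 2 arrays against 2, no exact permutation p can go below 0.333, so every call rests on the variance that limma pools across genes.

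The 2 targets were read on every array first. TIMELESS (chromosome 12, 56416363 to 56449426 in hg38) had log2 levels of 7.47 and 7.77 in CTRL at day 15, 6.36 and 5.52 in TIM-KD, 7.54 and 7.85 in ZEB1-KD, and 6.15 and 6.98 in ZEB1/TIM-KDs. At day 60 it read 9.96 and 10.17 in CTRL and 8.07 and 7.85 in TIM-KD. TIMELESS fell in TIM-KD cells at day 15 (3.20-fold, -1.68 ± 0.31, adjusted p = 0.00402) and at day 60 (4.30-fold, -2.11 ± 0.31, adjusted p = 0.000954; log2 fold change ± SE, n = 2 per group). It rose with time in the controls (2.45 ± 0.31, adjusted p = 0.000132), so that the knockdown arrays of day 60 lay above the control arrays of day 15. In ZEB1/TIM-KDs the TIMELESS decrease did not pass the test, either against control (-1.06 ± 0.31, adjusted p = 0.0660) or against ZEB1-KD (-1.13 ± 0.31, adjusted p = 0.176).

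ZEB1 (chromosome 10, 31318417 to 31529804) read 9.69 and 9.44 in CTRL at day 15, 7.41 and 7.58 in ZEB1-KD, and 7.81 and 7.48 in ZEB1/TIM-KDs. It fell in ZEB1-KD (4.2-fold, -2.07 ± 0.19, adjusted p = 0.000105) and in ZEB1/TIM-KDs (3.78-fold, -1.92 ± 0.19, adjusted p = 0.000148). In TIM-KD cells ZEB1 read 10.25 and 10.30 at day 15, above the controls (0.71 ± 0.19, adjusted p = 0.0290), a call that was lost whichever of the 4 arrays was left out (log2 fold change 0.59 to 0.84). At day 60 it read 8.65 and 8.65 in CTRL and 11.09 and 10.83 in TIM-KD, a rise of 4.96-fold, 2.31 ± 0.19 (adjusted p = 9.96e-06). The day 60 difference was larger than that of day 15 by 1.6 ± 0.26 (adjusted p = 0.00306). In the controls ZEB1 was lower at day 60 than at day 15 (-0.92 ± 0.19, adjusted p = 0.00393).

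**Figure D1:**
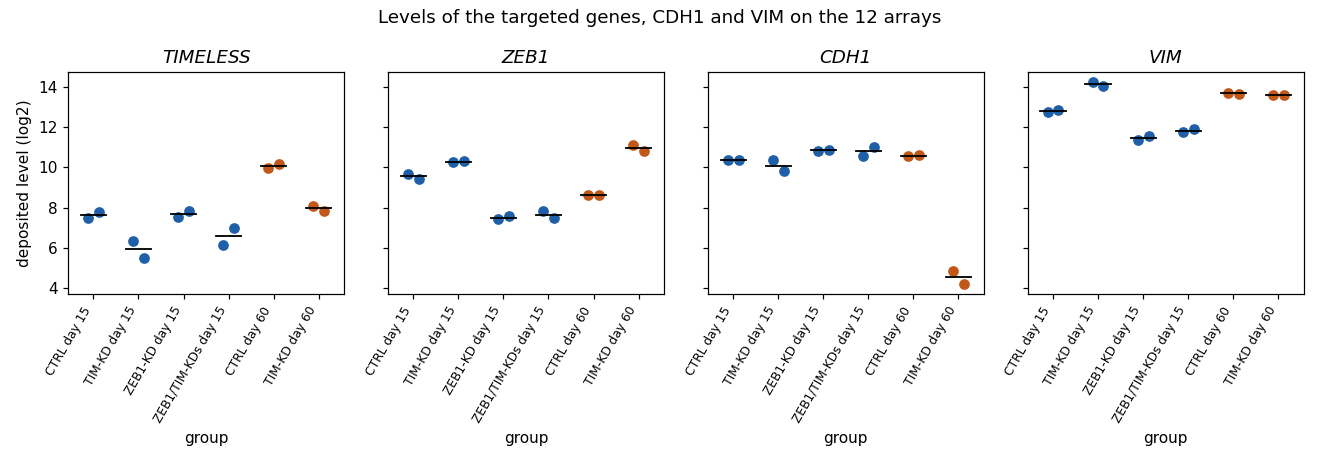
Deposited log2 levels of TIMELESS, ZEB1, CDH1 and VIM on each of the 12 arrays (points, blue at day 15 and orange at day 60), with a bar at each group mean (n = 2). CDH1 has group means from 10.09 to 10.84 in 5 groups and 4.53 in TIM-KD at day 60, while VIM has its highest mean, 14.15, in TIM-KD at day 15 and its lowest, 11.44, in ZEB1-KD.

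In TIM-KD cells at day 15, genes of cell division and DNA replication were higher than in the controls, and genes of the unfolded protein and integrated stress response were lower. The largest rises included NRP1, a co-receptor for VEGF and semaphorins (45.6-fold, 5.51 ± 0.39, adjusted p = 6.76e-06), SCG2, a secretory granule protein (35.1-fold, 5.14 ± 0.34), and IL7R, the interleukin 7 receptor alpha chain (29.2-fold, 4.87 ± 0.22). DKK1, a secreted Wnt antagonist, rose 24.7-fold, and FN1, fibronectin, 15.8-fold. Among the largest falls were the trypsinogen gene PRSS2 (27.2-fold, -4.77 ± 0.24, adjusted p = 1.26e-06), IGFBP1, which binds insulin-like growth factors (25.8-fold, -4.69 ± 0.25), and the complement regulator CD55 (11.2-fold, -3.49 ± 0.23). The chemokine gene CCL20 fell 8.69-fold. The control means of SCG2, DKK1 and FN1 lay under the dim limit of 4.78, so their fold changes are lower bounds.

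Of the genes in the mitosis list, 33 of 35 rose and 0 fell (33 and 0 adjusted over the list alone; median 1.82, adjusted p = 9.76e-79). List medians, and values after a gene name here and below, are log2 fold changes (± SE), or differences of them for interactions. The rises include the kinetochore gene CENPF (9.13-fold, 3.19 ± 0.18), the topoisomerase gene TOP2A (6.00-fold, 2.59 ± 0.16) and the spindle genes DLGAP5 (2.66) and TTK (2.45). In the DNA replication list 24 of 42 rose and 2 fell (29 and 2 adjusted over the list alone; median 0.80, adjusted p = 9.32e-14). TYMS, thymidylate synthase, rose by 2.02 ± 0.21, and RRM2, a ribonucleotide reductase subunit, by 1.63 ± 0.16. Among fork protection and replication checkpoint genes 6 of 21 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.49, adjusted p = 8.05e-05, adjusted p = 0.175 with an estimated correlation). CLSPN, the adaptor of the checkpoint kinase CHEK1, rose 7.78-fold. Of the homologous recombination and Fanconi anaemia repair genes 7 of 24 rose and 2 fell (9 and 2 adjusted over the list alone; median 0.27, adjusted p = 0.000766, adjusted p = 0.0832 with an estimated correlation).

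The unfolded protein and integrated stress response list moved the other way: 0 of 29 rose and 15 fell (1 and 19 adjusted over the list alone; median -0.87, adjusted p = 2.23e-17). DDIT4, an inhibitor of mTORC1 signalling, fell by 2.98 log2, TRIB3, a target of ATF4, by 2.74 and ATF3 by 2.55. In hypoxia and glycolysis 0 of 28 rose and 9 fell (0 and 13 adjusted over the list alone; median -0.38, adjusted p = 4.55e-09, adjusted p = 0.0722 with an estimated correlation). VEGFA (6.41-fold, -2.68 ± 0.17) and the collagen prolyl hydroxylase gene P4HA1 (-1.71 ± 0.19) fell. Among MYC targets and ribosome biogenesis genes 0 of 25 rose and 7 fell (0 and 10 adjusted over the list alone; median -0.51, adjusted p = 0.000171, adjusted p = 0.170 with an estimated correlation). MYC itself changed by -2.04 ± 0.22. Interferon response genes moved up as a list, in which 10 of 38 rose and 0 fell (10 and 0 adjusted over the list alone; median 0.40, adjusted p = 0.000292). SAMD9 (2.45), the RNA sensor gene RIGI (1.72) and the immunoproteasome gene PSMB9 (1.32) were among the rises. The mitosis, DNA replication, stress response and interferon calls held with an estimated correlation.

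In the core clock list 0 of 21 rose and 5 fell (0 and 7 adjusted over the list alone; median -0.33, adjusted p = 0.0200, adjusted p = 0.0722 with an estimated correlation). Of the epithelial junction and polarity genes 2 of 43 rose and 9 fell (3 and 11 adjusted over the list alone; median -0.26, adjusted p = 0.0110, adjusted p = 0.0582 with an estimated correlation). Both of these list calls were lost without TIM-KD replicate 2 (adjusted p = 0.0745 for the clock and 0.0584 for the epithelial list). The mesenchymal list did not pass: 6 of 36 rose and 2 fell (8 and 2 adjusted over the list alone, adjusted p = 0.0608). In it VIM, an intermediate filament gene, rose 2.58-fold, and the transcription factor gene SNAI2 fell (-2.31 ± 0.23).

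The lists that follow did not pass in TIM-KD cells at day 15. In sister chromatid cohesion 4 of 17 rose and 1 fell (4 and 1 adjusted over the list alone, adjusted p = 0.0600). In p53 targets 4 of 22 rose and 4 fell (5 and 4 adjusted over the list alone, adjusted p = 0.888). In Wnt targets and intestinal stem cell genes 4 of 25 rose and 4 fell (7 and 6 adjusted over the list alone, adjusted p = 0.153). In colonocyte and secretory differentiation 1 of 26 rose and 4 fell (1 and 4 adjusted over the list alone, adjusted p = 0.137). In NF-kB and inflammatory genes 3 of 28 rose and 2 fell (3 and 3 adjusted over the list alone, adjusted p = 0.585). In ERK output 4 of 29 rose and 6 fell (5 and 10 adjusted over the list alone, adjusted p = 0.840). For TGF-beta and YAP targets 5 of 24 rose and 3 fell (7 and 6 adjusted over the list alone, adjusted p = 0.570). For cholesterol synthesis 1 of 20 rose and 2 fell (1 and 4 adjusted over the list alone, adjusted p = 0.840). For oxidative phosphorylation 1 of 25 rose and 2 fell (1 and 2 adjusted over the list alone, adjusted p = 0.840). In senescence and secreted factors 3 of 17 rose and 2 fell (3 and 2 adjusted over the list alone, adjusted p = 0.840). Markers of other cell types showed few calls. In fibroblast and endothelial markers 1 of 19 rose and 0 fell (1 and 0 adjusted over the list alone, adjusted p = 0.840). In leukocyte markers 1 of 17 rose and 0 fell (1 and 0 adjusted over the list alone, adjusted p = 0.884). In neural and kidney markers of the virus packaging line 0 of 13 rose and 0 fell (0 and 0 adjusted over the list alone, adjusted p = 0.702).

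In all, 2418 of 21448 probe sets passed in this comparison, 1255 higher and 1163 lower. Higher calls made up 51.9%, and 43.1% with each array centred on its median, so the larger side depended on the scaling. Without CTRL replicate 1 the count was 1434, and without CTRL replicate 2 it was 1402. Of the 97 named genes called, 76 kept their call whichever of the 4 arrays was left out. ZEB1 is the gene printed above that did not.

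In ZEB1-KD cells single genes changed strongly against the controls, and no list call held with an estimated correlation. APCDD1, a membrane inhibitor of Wnt signalling (18.6-fold, 4.22 ± 0.34, adjusted p = 5.45e-05), LPAR6, a lysophosphatidic acid receptor (18.3-fold, 4.2 ± 0.29), and SERPINA1, alpha-1 antitrypsin (13.9-fold, 3.80 ± 0.32), had the largest rises. SLCO1B3, an organic anion transporter (63.3-fold, -5.99 ± 0.27, adjusted p = 6.11e-07), ANXA1, an annexin (18.9-fold, -4.24 ± 0.21), and CST7, cystatin F (17.3-fold, -4.12 ± 0.18), fell most. CDH1, which ZEB1 is known to repress, did not pass: its means were 10.35 in control and 10.84 in ZEB1-KD.

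Among epithelial junction and polarity genes 5 of 43 rose and 2 fell (7 and 2 adjusted over the list alone; median 0.09, adjusted p = 0.0164, adjusted p = 0.318 with an estimated correlation). MAL2, a trafficking protein of polarized cells, rose 7.36-fold, and CDH3, P-cadherin, by 2.11 ± 0.17 log2. In the mesenchymal list, which did not pass, 1 of 36 rose and 5 fell (1 and 8 adjusted over the list alone, adjusted p = 0.194). VIM fell 2.54-fold, and SNAI2 changed by -1.59 ± 0.23. In the Wnt targets and intestinal stem cell list 7 of 25 rose and 1 fell (10 and 3 adjusted over the list alone; median 0.18, adjusted p = 0.000306, adjusted p = 0.318 with an estimated correlation). LEF1, a transcription factor of the pathway (1.59 ± 0.21), and AXIN2, a feedback inhibitor (1.2 ± 0.19), rose. The unfolded protein and integrated stress response list shifted down, as 0 of 29 rose and 8 fell (1 and 15 adjusted over the list alone; median -0.54, adjusted p = 4.83e-06, adjusted p = 0.257 with an estimated correlation). DDIT4 changed by -2.12 ± 0.21 and TRIB3 by -1.49 ± 0.19. In mitosis 5 of 35 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.27, adjusted p = 0.000317, adjusted p = 0.318 with an estimated correlation). For MYC targets and ribosome biogenesis 0 of 25 rose and 5 fell (1 and 7 adjusted over the list alone; median -0.19, adjusted p = 0.0256, adjusted p = 0.492 with an estimated correlation). None of these 5 list calls held with an estimated correlation. The epithelial call was also lost without CTRL replicate 1 (adjusted p = 0.0874), and the MYC call without CTRL replicate 2 (0.0993) or ZEB1-KD replicate 1 (0.0636).

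In this comparison 1470 probe sets passed, 701 higher and 769 lower. Leaving out 1 array gave 522 (CTRL replicate 1), 534 (CTRL replicate 2), 429 (ZEB1-KD replicate 1) and 480 (ZEB1-KD replicate 2). The share of higher calls depended on the scaling of the arrays: it was 47.7%, and 35.9% with each array centred on its median.

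Cells with both knockdowns, set against the same controls, had more mitosis and Wnt genes higher than lower and more hypoxia genes lower than higher. LPAR6 (25.7-fold, 4.69 ± 0.29), DKK1 (at least 18.4-fold, 4.21 ± 0.24) and CDH3 (12.2-fold, 3.62 ± 0.17) rose, while SLCO1B3 (24.6-fold, -4.62 ± 0.27), IGFBP1 (21.5-fold, -4.43 ± 0.25) and CCL20 (9.25-fold, -3.21 ± 0.24) fell. In the mitosis list 13 of 35 rose and 0 fell (20 and 1 adjusted over the list alone; median 0.58, adjusted p = 2.65e-14, adjusted p = 0.0689 with an estimated correlation). TOP2A changed by 1.74 ± 0.16 and CENPF by 1.65 ± 0.18. In Wnt targets and intestinal stem cell genes 6 of 25 rose and 1 fell (8 and 2 adjusted over the list alone; median 0.15, adjusted p = 2.54e-07, adjusted p = 0.262 with an estimated correlation). LEF1 changed by 3.16 ± 0.21. For hypoxia and glycolysis 1 of 28 rose and 7 fell (1 and 16 adjusted over the list alone; median -0.54, adjusted p = 1.84e-06, adjusted p = 0.182 with an estimated correlation). The oxygen sensor gene EGLN3 changed by -1.45 ± 0.23. The unfolded protein and integrated stress response list did not pass: 3 of 29 rose and 3 fell (3 and 7 adjusted over the list alone, adjusted p = 0.310).

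Other lists gave calls in this comparison that were lost in part of the settings. Among epithelial genes 4 of 43 rose and 2 fell (4 and 3 adjusted over the list alone; median 0.18, adjusted p = 0.0251, adjusted p = 0.349 with an estimated correlation). This call was lost without CTRL replicate 1 (adjusted p = 0.174), without ZEB1/TIM-KDs replicate 2 (0.177) and without dim probe sets (0.0661). In colonocyte and secretory differentiation 0 of 26 rose and 3 fell (1 and 3 adjusted over the list alone; median -0.15, adjusted p = 0.0251, adjusted p = 0.262 with an estimated correlation), lost without CTRL replicate 1 (0.155) or ZEB1/TIM-KDs replicate 2 (0.122). Of the MYC targets and ribosome biogenesis genes 0 of 25 rose and 5 fell (1 and 6 adjusted over the list alone; median -0.25, adjusted p = 0.0251, adjusted p = 0.613 with an estimated correlation), lost without CTRL replicate 2 (0.0975) or ZEB1/TIM-KDs replicate 1 (0.390). Against control 1424 probe sets passed, 758 higher and 666 lower, with 531 without CTRL replicate 1, 576 without CTRL replicate 2 and 874 without ZEB1/TIM-KDs replicate 2. The share of higher calls was 53.2%, and 40.7% with each array centred on its median.

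Few genes separated ZEB1/TIM-KDs from ZEB1-KD, the comparison that reads the TIM knockdown in ZEB1 knockdown cells. TIMELESS itself was not called here (-1.13 ± 0.31, adjusted p = 0.176), so a low count does not show that the knockdown has little effect in these cells. ANXA1 (30.4-fold, 4.93 ± 0.21, adjusted p = 9.24e-07), DKK1 (9.19-fold, 3.20 ± 0.24, adjusted p = 0.000238) and EREG, an EGF receptor ligand (at least 6.68-fold, 2.74 ± 0.28), were higher. So were GASK1B (2.71 ± 0.24), the bombesin receptor gene GRPR (at least 2.58 ± 0.26) and the Wnt antagonist gene DKK4 (2.25 ± 0.23). These 6 are the named genes called here that kept their call whichever array was left out, of 17. In all 79 probe sets passed, 52 higher and 27 lower, and the count fell to 13 without ZEB1-KD replicate 1, 7 without ZEB1-KD replicate 2 and 42 without ZEB1/TIM-KDs replicate 1. Without ZEB1/TIM-KDs replicate 2 61 passed, of which 49.2% were higher, against 65.8% with all arrays.

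As lists, stress response and mitosis genes shifted up in ZEB1/TIM-KDs against ZEB1-KD, with no member called over all probe sets. In the unfolded protein and integrated stress response list 0 of 29 rose and 0 fell (14 and 1 adjusted over the list alone; median 0.46, adjusted p = 6.63e-07, adjusted p = 0.132 with an estimated correlation). In mitosis 0 of 35 rose and 0 fell (4 and 0 adjusted over the list alone; median 0.32, adjusted p = 7.12e-07, adjusted p = 0.153 with an estimated correlation). Hypoxia and glycolysis genes shifted down, though 0 of 28 rose and 0 fell (0 and 0 adjusted over the list alone; median -0.30, adjusted p = 0.000851, adjusted p = 0.258 with an estimated correlation, and 0.0727 without ZEB1/TIM-KDs replicate 1). In colonocyte and secretory differentiation 1 of 26 rose and 0 fell (1 and 6 adjusted over the list alone; median -0.15, adjusted p = 0.0135, adjusted p = 0.182 with an estimated correlation). It lost the call without ZEB1-KD replicate 2 (0.0722) or ZEB1/TIM-KDs replicate 2 (0.183).

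Set against TIM-KD instead, the cells with both knockdowns had lower mitosis and replication genes and higher stress response and epithelial genes. IL7R (29.6-fold, -4.89 ± 0.22, adjusted p = 1.31e-06), SCG2 (at least 23.3-fold), NRP1 (19.5-fold, -4.29 ± 0.39) and FN1 (11.6-fold, -3.54 ± 0.21) fell. LPAR6 (11.4-fold, 3.52 ± 0.29), APCDD1 (9.03-fold, 3.18 ± 0.34), SERPINA1 (8.97-fold, 3.17 ± 0.32) and HEY2, a Notch target (7.16-fold, 2.84 ± 0.19), rose. VIM was lower (5.03-fold, -2.33 ± 0.17), and so was S100A4, a calcium-binding protein of motile cells (5.22-fold, -2.39 ± 0.21).

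In mitosis 0 of 35 rose and 29 fell (0 and 34 adjusted over the list alone; median -1.22, adjusted p = 4.11e-50). DLGAP5 changed by -1.93 ± 0.17 and the securin gene PTTG1 by -1.77 ± 0.20. In DNA replication 0 of 42 rose and 16 fell (0 and 24 adjusted over the list alone; median -0.74, adjusted p = 3.71e-17). Of the unfolded protein and integrated stress response genes 14 of 29 rose and 0 fell (17 and 0 adjusted over the list alone; median 0.67, adjusted p = 2.88e-20), ATF3 (2.07 ± 0.22) and TRIB3 (1.77 ± 0.19) among them. In epithelial junction and polarity 10 of 43 rose and 1 fell (17 and 1 adjusted over the list alone; median 0.41, adjusted p = 8.73e-10), including MAL2 (2.80 ± 0.23) and the desmosomal cadherin gene DSC2 (1.73 ± 0.23). These 4 list calls held with an estimated correlation. The mesenchymal list shifted down by the test and by its mean (-0.35) while its median was 0.01. In it 1 of 36 rose and 6 fell (1 and 6 adjusted over the list alone), with adjusted p = 0.000544 and adjusted p = 0.222 with an estimated correlation.

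Further lists separated ZEB1/TIM-KDs from TIM-KD without holding when the correlation was estimated. In homologous recombination and Fanconi anaemia repair 0 of 24 rose and 6 fell (0 and 6 adjusted over the list alone; median -0.38, adjusted p = 0.000659, adjusted p = 0.0729 with an estimated correlation). In Wnt targets and intestinal stem cell genes 6 of 25 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.13, adjusted p = 0.000693, adjusted p = 0.178 with an estimated correlation, and 0.0557 without ZEB1/TIM-KDs replicate 2). For fork protection 0 of 21 rose and 5 fell (1 and 7 adjusted over the list alone; median -0.20, adjusted p = 0.00606, adjusted p = 0.338 with an estimated correlation). It lost the call without TIM-KD replicate 1 (0.257) or ZEB1/TIM-KDs replicate 1 (0.20). In the core clock list 3 of 21 rose and 0 fell (6 and 1 adjusted over the list alone; median 0.17, adjusted p = 0.0196, adjusted p = 0.0813 with an estimated correlation). The clock call was lost without TIM-KD replicate 2 (0.159) or ZEB1/TIM-KDs replicate 2 (0.120). Among interferon response genes 0 of 38 rose and 2 fell (0 and 4 adjusted over the list alone; median -0.14, adjusted p = 0.0395, adjusted p = 0.0813 with an estimated correlation). The interferon call was lost without TIM-KD replicate 1 (0.0566), ZEB1/TIM-KDs replicate 1 (0.0553) or ZEB1/TIM-KDs replicate 2 (0.0877). Here 1187 probe sets passed, 562 higher and 625 lower, with 683 without TIM-KD replicate 2 and 726 without ZEB1/TIM-KDs replicate 1.

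The TIM knockdown effect itself differed between cells without and with the ZEB1 knockdown. This interaction is the log2 fold change of ZEB1/TIM-KDs against ZEB1-KD minus that of TIM-KD against control. It was negative for SCG2 (-4.53 ± 0.48, adjusted p = 0.000938), IL7R (-4.14 ± 0.31), NRP1 (-3.69 ± 0.55) and the histone gene H2BC14 (-4.46 ± 0.49). It was positive for IGFBP1 (4.01 ± 0.35, adjusted p = 0.000405), the calcium channel gene TRPV6 (3.77 ± 0.56), PRSS2 (3.71 ± 0.35) and DDIT4 (3.54 ± 0.30). For these genes the change on adding the TIM hairpin was smaller or of the other sign in cells that also carried the ZEB1 hairpin. A smaller change need not mean a level nearer to control. IGFBP1 fell against control to a like extent in TIM-KD and in ZEB1/TIM-KDs, so it was already low in ZEB1-KD. A state of the control cultures also enters this interaction and cannot be told apart from it. Many genes named for this interaction lost their call when a single array was left out. SCG2 and IL7R had a group mean under 4.78, so the size of their interaction is uncertain. The interaction of TIMELESS (0.55 ± 0.44, adjusted p = 0.591) and of ZEB1 (-0.56 ± 0.26, adjusted p = 0.315) did not pass.

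Mitosis genes carried the largest negative list interaction: 0 of 35 were positive and 24 negative (0 and 32 adjusted over the list alone; median -1.47, adjusted p = 4.98e-49). CENPF was at -2.54 ± 0.26 and TOP2A at -2.11 ± 0.22. In DNA replication 1 of 42 were positive and 6 negative (2 and 23 adjusted over the list alone; median -0.90, adjusted p = 6.55e-13). The unfolded protein and integrated stress response had the largest positive one: 16 of 29 were positive and 0 negative (21 and 0 adjusted over the list alone; median 1.21, adjusted p = 1.45e-29). TRIB3 was at 3.26 ± 0.27, and DNAJB9, a chaperone of the endoplasmic reticulum, at 2.43 ± 0.34. These 3 held with an estimated correlation, with adjusted p = 0.00438 for mitosis, 0.0440 for DNA replication and 0.00438 for the stress response. Of the fork protection genes 0 of 21 were positive and 3 negative (0 and 6 adjusted over the list alone; median -0.50, adjusted p = 0.000128, adjusted p = 0.233 with an estimated correlation). Of the homologous recombination genes 0 of 24 were positive and 2 negative (2 and 5 adjusted over the list alone; median -0.46, adjusted p = 0.00513, adjusted p = 0.127 with an estimated correlation). Among MYC targets 3 of 25 were positive and 0 negative (5 and 0 adjusted over the list alone; median 0.45, adjusted p = 0.000342, adjusted p = 0.230 with an estimated correlation). In hypoxia and glycolysis 7 of 28 were positive and 0 negative (7 and 0 adjusted over the list alone; median 0.18, adjusted p = 0.000981, adjusted p = 0.295 with an estimated correlation). In the core clock 2 of 21 were positive and 0 negative (4 and 0 adjusted over the list alone; median 0.42, adjusted p = 0.00513, adjusted p = 0.0747 with an estimated correlation).

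Among interferon response genes 0 of 38 were positive and 1 negative (0 and 1 adjusted over the list alone; median -0.16, adjusted p = 0.0251, adjusted p = 0.115 with an estimated correlation). This call was lost without CTRL replicate 1 (0.0928), without ZEB1/TIM-KDs replicate 2 (0.0559) and after quantile normalization (0.0510). Among epithelial genes 4 of 43 were positive and 0 negative (4 and 0 adjusted over the list alone; median 0.14, adjusted p = 0.0306, adjusted p = 0.127 with an estimated correlation). The epithelial call was lost without CTRL replicate 2 (0.0902), TIM-KD replicate 2 (0.118), ZEB1-KD replicate 2 (0.0933) or ZEB1/TIM-KDs replicate 2 (0.178). The interaction passed for 859 probe sets, 434 positive and 425 negative. Leaving out 1 array gave 419 (CTRL replicate 1), 363 (CTRL replicate 2), 565 (TIM-KD replicate 1), 291 (ZEB1-KD replicate 1) and 335 (ZEB1-KD replicate 2). Positive values made up 50.5% of the calls, and 61.2% with each array centred on its median.

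**Figure D2:**
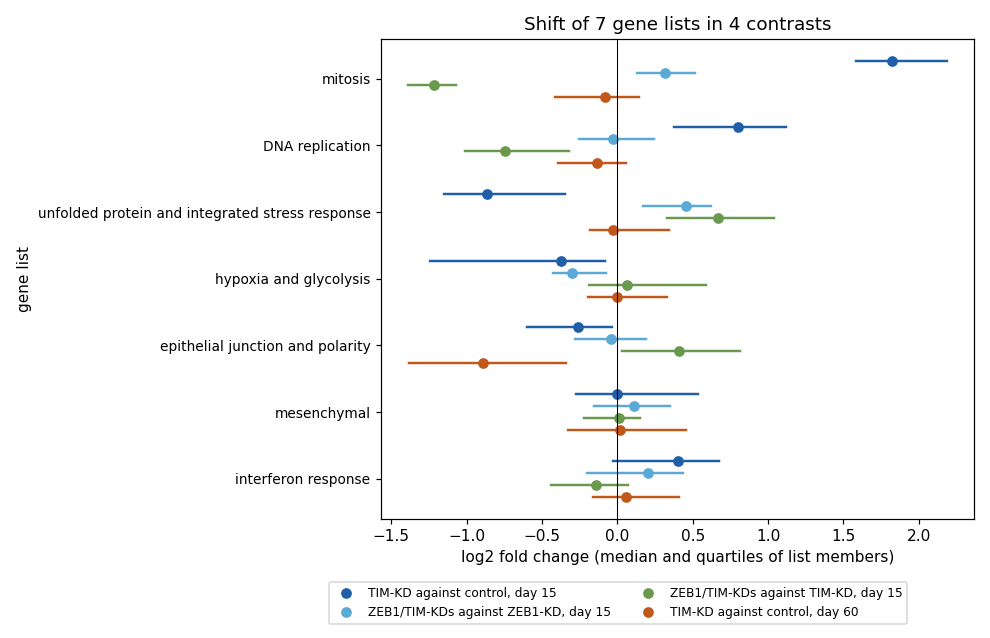
Median log2 fold change of 7 gene lists in 4 comparisons, with bars over the quartiles of the list members. The mitosis list has its highest median, 1.82, and the unfolded protein and integrated stress response list its lowest, -0.87, in TIM-KD against control at day 15, while the epithelial list has its lowest, -0.90, in TIM-KD against control at day 60.

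At day 60 the list with the smallest adjusted p in TIM-KD cells against their controls was that of epithelial genes, which fell. CDH1, E-cadherin (chromosome 16, 68737292 to 68835537), fell at least 66.3-fold (-6.05 ± 0.25, adjusted p = 5.16e-08), to 4.83 and 4.23 on the 2 arrays. ST14, the membrane protease matriptase (47.3-fold, -5.57 ± 0.23), GJB1, a gap junction gene (41.8-fold, -5.39 ± 0.16), and ESRP1, a splicing regulator of epithelial cells (21.7-fold, -4.44 ± 0.16), fell as well. TRIM29 fell 96.0-fold. CALB1, the calcium-binding protein calbindin, had the largest fall as measured (140-fold, -7.13 ± 0.21, adjusted p = 6.98e-09). DACH1, a transcriptional repressor (94.7-fold, 6.57 ± 0.24, adjusted p = 2.94e-08), and CHST11, a chondroitin sulfotransferase (53.6-fold, 5.75 ± 0.22), rose. So did the protocadherin gene PCDH9 (42.2-fold, 5.40 ± 0.19) and the collagen lysyl hydroxylase gene PLOD2 (26.8-fold, 4.75 ± 0.27). The mean of CDH1 in TIM-KD and those of DACH1 and PCDH9 in control lay under the dim limit of 4.78, so these fold changes are lower bounds.

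Among epithelial junction and polarity genes 0 of 43 rose and 25 fell (0 and 27 adjusted over the list alone; median -0.90, adjusted p = 6.91e-38), with SPINT2, an inhibitor of matriptase, at -2.73 ± 0.19. This was the day 60 list call that held with an estimated correlation. In the mesenchymal list, which did not pass, 2 of 36 rose and 2 fell (3 and 4 adjusted over the list alone, adjusted p = 0.702). PRRX1, a transcription factor (at least 1.88 ± 0.26), and FN1 (1.22 ± 0.21) rose, and S100A4 fell (-3.60 ± 0.21). VIM had means of 13.67 in control and 13.58 in TIM-KD. In colonocyte and secretory differentiation 0 of 26 rose and 7 fell (0 and 7 adjusted over the list alone). The mucin gene MUC13 (-4.97 ± 0.19), the microvillus gene VIL1 (-2.85 ± 0.25) and the intestinal transcription factor gene CDX2 (-1.82 ± 0.22) fell. Its mean was -0.55 and the test gave a downward shift, while its median was 0.07 (adjusted p = 2.31e-05, adjusted p = 0.523 with an estimated correlation).

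Among NF-kB and inflammatory genes 0 of 28 rose and 6 fell (0 and 6 adjusted over the list alone; median -0.15, adjusted p = 0.00211, adjusted p = 0.679 with an estimated correlation). CCL20, with a TIM-KD mean of 4.72, fell by at least 3.59 log2, and CXCL8 fell by 2.52 log2. For TGF-beta and YAP targets 0 of 24 rose and 6 fell (0 and 6 adjusted over the list alone), with ID1, a target of BMP signalling, at -2.96 ± 0.25. The median of this list was 0 and its mean -0.31 (adjusted p = 0.0181, adjusted p = 0.523 with an estimated correlation). In oxidative phosphorylation 0 of 25 rose and 2 fell (1 and 5 adjusted over the list alone; median -0.22, adjusted p = 0.0440, adjusted p = 0.679 with an estimated correlation). It lost the call without CTRL replicate 2 (0.138), TIM-KD replicate 1 (0.129), dim probe sets (0.131) or after quantile normalization (0.318). The 4 lists that held with an estimated correlation at day 15 did not pass at day 60. In mitosis 2 of 35 rose and 1 fell (2 and 1 adjusted over the list alone, adjusted p = 0.702), with a median of -0.08. In DNA replication 1 of 42 rose and 3 fell (2 and 3 adjusted over the list alone, adjusted p = 0.270). In the unfolded protein and integrated stress response 4 of 29 rose and 1 fell (6 and 1 adjusted over the list alone, adjusted p = 0.702), and in interferon response 3 of 38 rose and 0 fell (3 and 0 adjusted over the list alone, adjusted p = 0.702). In all 1815 probe sets passed, 943 higher and 872 lower. The share of higher calls was 52.0%, and 42.3% with each array centred on its median, which turns the larger side. Leaving out 1 array gave 946 (CTRL replicate 1), 944 (CTRL replicate 2), 938 (TIM-KD replicate 1) and 988 (TIM-KD replicate 2).

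Part of the day 60 difference followed chromosomes, a grouping chosen after the data were seen. Among 6872 genes with a mean log2 level of at least 8, the 488 on chromosome 2 had a median log2 fold change of 0.54 in TIM-KD against control, and 92.4% of them were higher. The 210 on chromosome 20 had a median of -0.74, and 91.9% were lower. On chromosome 7 before 60 Mb 121 genes had a median of 0.56, against -0.08 for the rest of that chromosome. The median was -0.61 over 78 genes between 50 and 90 Mb of chromosome 5, and -0.60 over 46 genes between 110 and 130 Mb of chromosome 10. In the day 15 comparison of TIM-KD with control the medians were -0.06 on chromosome 2 and -0.02 on chromosome 20. Between the controls of day 60 and day 15 the regions of chromosomes 10 and 7 moved as well, by 0.60 and -0.31, opposite in sign to their day 60 shifts. Over the other 18 chromosomes the day 60 medians lay between -0.16 and 0.01. The lowest was that of chromosome 11, where 67.3% of 437 genes were lower. It was close to that of chromosome 10 as a whole (-0.15, 66.9% lower). Chromosome 11 was kept in the runs that left chromosomes out. As deviations from the mean of the 12 arrays, both TIM-KD arrays of day 60 carried the shifts of chromosome 2 (0.51 and 0.49) and chromosome 20 (-0.64 and -0.58). Both control arrays of day 60 carried that of the chromosome 10 region (0.57 and 0.48). The replicates of a group may therefore share a population of cells, and the p-values of day 60 may not measure the spread between separate cultures. Of the 1615 named genes called at day 60, 626 (38.8%) lie on chromosomes 2, 5, 7, 10 and 20, which hold 21.9% of the genes. Without these 5 chromosomes 1070 probe sets passed, and the TGF-beta and YAP list no longer did (adjusted p = 0.283).

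**Figure D3:**
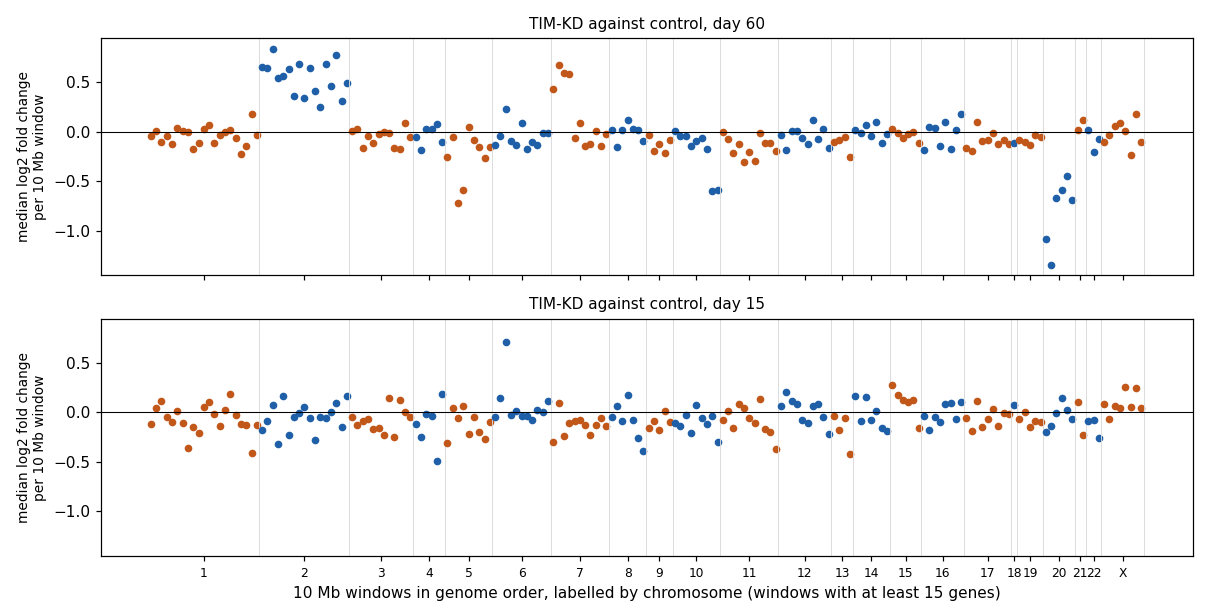
Median log2 fold change of TIM-KD against control in windows of 10 Mb with at least 15 genes, in genome order, at day 60 (top) and day 15 (bottom). At day 60 all 17 windows of chromosome 2 lie above 0.2 and all 6 of chromosome 20 below -0.2, with medians over the genes of 0.54 and -0.74.

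The TIM-KD effect at day 60 was then tested against that at day 15. This difference of log2 fold changes was most negative for CALB1 (-9.06 ± 0.30, adjusted p = 4.62e-08), which was higher in TIM-KD at day 15 and lower at day 60, LRRTM1 (-7.13 ± 0.47) and IL7R (-6.85 ± 0.31). CDH1 (-5.79 ± 0.35, adjusted p = 4.83e-06), ST14 (-4.99 ± 0.33) and ESRP1 (-3.40 ± 0.23) were negative as well. DACH1 (6.41 ± 0.34, adjusted p = 1.99e-06) and PLOD2 (5.22 ± 0.38) were among the largest positive values, and IGFBP1 (5.02 ± 0.35) and EGLN3 (4.62 ± 0.33) were positive as well. TIMELESS itself did not differ by the test (-0.43 ± 0.44, adjusted p = 0.661). Of these genes CDH1, DACH1, IGFBP1 and EGLN3 had a group mean under 4.78, which makes the size of their difference uncertain.

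In mitosis 0 of 35 were positive and 31 negative (0 and 33 adjusted over the list alone; median -1.82, adjusted p = 2.79e-51), as in KIF20A (-3.77 ± 0.36) and TOP2A (-2.44 ± 0.22). In epithelial junction and polarity 0 of 43 were positive and 13 negative (1 and 16 adjusted over the list alone; median -0.44, adjusted p = 5.7e-15). For DNA replication 1 of 42 were positive and 17 negative (2 and 28 adjusted over the list alone; median -1, adjusted p = 5.71e-13), with PCNA, the replication clamp, at -1.87 ± 0.24. For the unfolded protein and integrated stress response 13 of 29 were positive and 0 negative (20 and 0 adjusted over the list alone; median 1.00, adjusted p = 7.79e-13). These 4 held with an estimated correlation, with adjusted p = 0.00468 for mitosis, 0.00471 for epithelial genes, 0.0253 for DNA replication and 0.0125 for the stress response. In hypoxia and glycolysis 6 of 28 were positive and 0 negative (8 and 1 adjusted over the list alone; median 0.29, adjusted p = 9.72e-06, adjusted p = 0.150 with an estimated correlation). In fork protection 0 of 21 were positive and 5 negative (0 and 8 adjusted over the list alone; median -0.52, adjusted p = 0.00152, adjusted p = 0.246 with an estimated correlation). In homologous recombination 2 of 24 were positive and 3 negative (2 and 5 adjusted over the list alone; median -0.66, adjusted p = 0.00686, adjusted p = 0.0992 with an estimated correlation). In TGF-beta and YAP targets 0 of 24 were positive and 5 negative (0 and 5 adjusted over the list alone; median -0.31, adjusted p = 0.00686, adjusted p = 0.0992 with an estimated correlation).

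Another 8 lists passed in this difference of effects and lost the call for at least 1 array left out. The core clock (median 0.37, adjusted p = 0.0111, adjusted p = 0.0992 with an estimated correlation) and MYC targets (median 0.37, adjusted p = 0.0249, adjusted p = 0.332 with an estimated correlation) had positive medians. Sister chromatid cohesion (median -0.33, adjusted p = 0.0282, adjusted p = 0.332 with an estimated correlation) and oxidative phosphorylation (median -0.12, adjusted p = 0.0354, adjusted p = 0.332 with an estimated correlation) had negative ones. So did interferon response (median -0.26, adjusted p = 0.0424, adjusted p = 0.0992 with an estimated correlation) and the mesenchymal list (median -0.09, adjusted p = 0.0462, adjusted p = 0.305 with an estimated correlation). The other 2 had a median and a mean of opposite sign. Colonocyte differentiation had a median of 0.20 and a mean of -0.33 (adjusted p = 0.0350, adjusted p = 0.332 with an estimated correlation). For NF-kB and inflammatory genes the values were 0.15 and -0.30 (adjusted p = 0.0424, adjusted p = 0.590 with an estimated correlation). Without TIM-KD day 15 replicate 2 adjusted p was 0.0595 for the clock, 0.154 for MYC targets, 0.137 for colonocyte and 0.235 for NF-kB. Without TIM-KD day 15 replicate 1 it was 0.133 for cohesion, 0.130 for oxidative phosphorylation and 0.0942 for the mesenchymal list. Interferon lost its call without CTRL day 15 replicate 1 (0.0882), CTRL day 60 replicate 1 (0.0637), TIM-KD day 15 replicate 2 (0.0672) and TIM-KD day 60 replicates 1 (0.0578) and 2 (0.0576). Without chromosomes 2, 5, 7, 10 and 20 the calls of interferon (0.125), colonocyte (0.0667), MYC targets (0.0667), NF-kB (0.0513), cohesion (0.0584) and the mesenchymal list (0.173) were lost.

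The effects of day 60 and day 15 differed for 1723 probe sets, 819 positive and 904 negative. Leaving out 1 array gave 1119 (CTRL day 15 replicate 1), 973 and 933 (CTRL day 60 replicates 1 and 2), and 1012 and 1049 (TIM-KD day 60 replicates 1 and 2). Without chromosomes 2, 5, 7, 10 and 20 the count was 1104.

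The day 60 controls differed from the day 15 controls in more genes than passed in any knockdown comparison. Cell division and replication genes were higher at day 60, and stress response, hypoxia and ERK output genes were lower. LPAR6 (66.0-fold, 6.05 ± 0.29, adjusted p = 1.18e-07), H2BC14 (58.3-fold, 5.87 ± 0.35) and CDCA3, a cell division gene (at least 30.7-fold, 4.94 ± 0.30), rose most. DDIT4 (74.8-fold, -6.23 ± 0.21, adjusted p = 9.47e-09), CAMK2N1, an inhibitor of CaM kinase II (66.0-fold, -6.05 ± 0.19), and PROM1, prominin (64.2-fold, -6.01 ± 0.29), fell most. The glucose transporter gene SLC2A3 fell 63.3-fold.

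In mitosis 35 of 35 rose and 0 fell (35 and 0 adjusted over the list alone; median 2.73, adjusted p = 3.3e-88). In DNA replication 37 of 42 rose and 0 fell (38 and 1 adjusted over the list alone; median 1.69, adjusted p = 6.67e-39). CCNA2, cyclin A2, changed by 3.64 ± 0.18 and GINS2, a helicase subunit, by 3.99 ± 0.24. In the unfolded protein and integrated stress response 0 of 29 rose and 27 fell (0 and 27 adjusted over the list alone; median -1.69, adjusted p = 2.05e-51). CHAC1 changed by -4.30 ± 0.18 and TRIB3 by -4.59 ± 0.19. In hypoxia and glycolysis 1 of 28 rose and 18 fell (1 and 20 adjusted over the list alone; median -1.51, adjusted p = 7.58e-31), VEGFA at -4.31 ± 0.17. Among ERK output genes 1 of 29 rose and 19 fell (2 and 22 adjusted over the list alone; median -1.46, adjusted p = 3.6e-20), including the phosphatase gene DUSP5 (-4.38 ± 0.21). In fork protection 16 of 21 rose and 0 fell (16 and 0 adjusted over the list alone; median 1.21, adjusted p = 2.14e-12). In homologous recombination 18 of 24 rose and 3 fell (18 and 3 adjusted over the list alone; median 1.6, adjusted p = 5.4e-11). In the core clock 1 of 21 rose and 8 fell (1 and 8 adjusted over the list alone; median -0.41, adjusted p = 0.000607). These 8 held with an estimated correlation and with each array left out.

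Another 7 lists passed with time in the controls and did not hold with an estimated correlation. Among cohesion genes 8 of 17 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.63, adjusted p = 6.4e-07, adjusted p = 0.0916 with an estimated correlation). Among oxidative phosphorylation genes 9 of 25 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.43, adjusted p = 0.00112, adjusted p = 0.0706 with an estimated correlation). Among MYC targets 6 of 25 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.47, adjusted p = 0.00213, adjusted p = 0.145 with an estimated correlation). Among cholesterol synthesis genes 7 of 20 rose and 1 fell (8 and 2 adjusted over the list alone; median 0.24, adjusted p = 0.0162, adjusted p = 0.0621 with an estimated correlation). Among p53 targets 3 of 22 rose and 9 fell (4 and 9 adjusted over the list alone; median -0.29, adjusted p = 0.00112, adjusted p = 0.0714 with an estimated correlation). Of the TGF-beta and YAP targets 2 of 24 rose and 9 fell (3 and 9 adjusted over the list alone; median -0.37, adjusted p = 0.00152, adjusted p = 0.0842 with an estimated correlation), and without chromosomes 2, 5, 7, 10 and 20 adjusted p was 0.0514. Of the NF-kB and inflammatory genes 1 of 28 rose and 9 fell (1 and 11 adjusted over the list alone; median -0.53, adjusted p = 0.00158, adjusted p = 0.139 with an estimated correlation). In all 4682 probe sets passed, 2306 higher and 2376 lower, with 2951 without CTRL day 60 replicate 1 and 2958 without replicate 2. The share of higher calls was 49.3%, and 59.6% with each array centred on its median. Day 15 and day 60 were sampled from cultures whose handling in between is not given in the sources used here.

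Comparisons that share no array were set side by side over all genes. The TIM-KD effect at day 15 and the effect of adding TIM-KD to ZEB1-KD had a Pearson correlation of 0.211 (Spearman 0.0964). Of the genes called in both, 45 changed the same way and 3 the opposite way. Chance would give 3.04 higher, 1.46 lower and 4.40 opposite. Between the TIM-KD effects of day 15 and day 60 the correlation was 0.183 (Spearman 0.126), with 425 genes called the same way and 125 the opposite way (chance would give 55.2 higher, 47.3 lower and 102.2 opposite). The ZEB1-KD effect and that of adding ZEB1-KD to TIM-KD had a correlation of 0.210 (Spearman 0.107), with 294 the same way and 80 the opposite way (chance would give 18.4 higher, 22.4 lower and 40.6 opposite). LPAR6, APCDD1 and SERPINA1 rose and SLCO1B3 and VIM fell in both of these. Leaving out 1 array moved each correlation. Without ZEB1/TIM-KDs replicate 2 the first was 0.133 and the third 0.120, and without TIM-KD day 15 replicate 2 the second was 0.115 and the third 0.132.

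Contrasts that share their control arrays are correlated by construction. TIM-KD and ZEB1-KD against the same controls had a correlation of 0.459, where simulated data with no effect gave 0.501. For ZEB1-KD and ZEB1/TIM-KDs the values were 0.743 and 0.50, for TIM-KD and ZEB1/TIM-KDs 0.621 and 0.499, and for TIM-KD at day 15 and the controls of day 60 0.501 and 0.50. The covariance between TIM-KD and ZEB1-KD effects was 0.114, against 0.0296 in the simulations. For the other pairs, in the order above, it was 0.1564, 0.151 and 0.1985, against 0.0296, 0.02951 and 0.02958. A correlation near 0.50 therefore does not show that sharing alone produced it. The excess can also come from a state of the shared control cultures, which these contrasts cannot separate from like effects. With 2 control arrays the controls cannot be split so that each comparison keeps 2 of its own.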

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

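All tests of explanations in this part were chosen only after the result was seen. The results below stand out because the effect of the TIM knockdown differed, by a test of the difference itself, between cells without and with the ZEB1 knockdown or between day 60 and day 15.

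Between cells without and with the ZEB1 knockdown the effect differed for 859 probe sets. List medians of this interaction were -1.47 for mitosis, -0.90 for DNA replication, -0.50 for fork protection, -0.46 for homologous recombination and -0.16 for interferon response. They were 1.21 for the unfolded protein and integrated stress response, 0.45 for MYC targets, 0.42 for the core clock, 0.18 for hypoxia and glycolysis and 0.14 for epithelial genes. With an estimated correlation 3 of these 10 kept their call. Many of the genes named for the interaction lost their call when a single array was left out. A state of the control cultures also enters the interaction and cannot be told apart from it. The interaction in log2 was positive for IGFBP1 (4.01), TRPV6 (3.77), PRSS2 (3.71), DDIT4 (3.54), CD55 (2.86), CCL20 (2.69), LURAP1L (2.55), DKK4 (2.20) and GRAMD1B (1.92). It was negative for SCG2 (-4.53), H2BC14 (-4.46), IL7R (-4.14), NRP1 (-3.69), ISM1 (-3.36), LRRTM1 (-2.36), GASK1B (-1.57) and DKK1 (-1.43). The sizes for SCG2, IL7R and DKK1 are uncertain, since a group mean of each lies under the dim limit of 4.78.

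Between day 60 and day 15 the TIM-KD effect differed for 1723 probe sets. Median differences were -1.82 for mitosis, -1 for DNA replication, -0.66 for homologous recombination, -0.52 for fork protection, -0.44 for epithelial genes, -0.33 for cohesion and -0.31 for TGF-beta and YAP targets. Interferon response (-0.26), oxidative phosphorylation (-0.12) and mesenchymal genes (-0.093) were negative as well. Positive medians were 1.00 for the unfolded protein and integrated stress response, 0.37 for the core clock, 0.37 for MYC targets, 0.29 for hypoxia and glycolysis, 0.20 for colonocyte differentiation and 0.15 for NF-kB genes. The last 2 have negative means and a downward test. With an estimated correlation 4 of these 16 kept their call. Positive differences in log2 were DACH1 (6.41), PLOD2 (5.22), ADAMTS19 (5.12), IGFBP1 (5.02), CAMK4 (4.27), OSBPL6 (4.12), PCDH9 (4.05), CHST11 (3.99), TRPV6 (3.70), ZC4H2 (3.51), LURAP1L (3.32), IGFBP3 (2.53), PRSS2 (1.96), ZEB1 (1.6) and CD55 (1.43). Negative ones were CALB1 (-9.06), LRRTM1 (-7.13), IL7R (-6.85), GASK1B (-6.46), NRP1 (-5.92), CDH1 (-5.79), TRIM29 (-5.70), GFRA3 (-5.19), ST14 (-4.99), GJB1 (-4.5), MUC13 (-4.28), TC2N (-3.35), ANXA1 (-3.33), ISM1 (-3.13) and DKK1 (-1.44). For the same reason the sizes for ADAMTS19, CDH1, DACH1, DKK1, IGFBP1, PCDH9 and TRPV6 are uncertain. The controls themselves differed between the days for 4682 probe sets, with mitosis and replication genes higher and stress response genes lower at day 60. A changed control baseline therefore cannot be told apart from a changed effect of the knockdown.

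The first pattern is the rise of mitosis genes with lower stress response genes in TIM-KD cells at day 15. A growth or stress state of the control cultures alone would raise the mitosis list as much in ZEB1-KD against the same controls. There its median was 0.27 with an upper quartile of 0.43. This argues against it as the only cause, provided that the ZEB1 knockdown does not itself lower these genes, which the design cannot show. Quartiles here describe the spread over list members, not between arrays. The list also shifted up in ZEB1/TIM-KDs against these controls, so a part played by their state stays open. An effect of the TIM knockdown whatever the ZEB1 level would also show in ZEB1/TIM-KDs against ZEB1-KD. There the stress response median was 0.46 (lower quartile 0.17), the other sign than in TIM-KD. The mitosis median was 0.32 (upper quartile 0.52), where a rise in proportion to the fall of TIMELESS, taken 1 SE smaller, needs 0.89. These values go against such an effect but do not settle it. No member of either list was called there over all probe sets, and neither list call held with an estimated correlation. The state of the controls stays open for the stress response list, with medians of -0.54 in ZEB1-KD and -0.87 in TIM-KD. That list did not pass in ZEB1/TIM-KDs against the same controls, which goes against it as the only cause, though a list that does not pass is not shown to be unchanged. A mitosis effect out of proportion to TIMELESS also stays open, since the fall of TIMELESS in ZEB1/TIM-KDs was smaller and not called (-1.13, limma adjusted p = 0.176). A growth state of the TIM-KD cultures for reasons other than the knockdown cannot be told apart, with a correlation of 0.376 over the called genes with control day 60 minus ZEB1-KD day 15 and the same sign for 59.6%.

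The second pattern is the shift of genes of whole chromosomes in TIM-KD cells at day 60. Scaling acts on a whole array, and on the TIM-KD arrays of day 60 chromosome 2 lay high while chromosome 20 lay low, which argues against scaling. After quantile normalization 93.9% of chromosome 2 genes stayed higher, but RMA had already quantile normalized the deposited values, so this adds little. Change in a few neighbouring genes is argued against, since 100% of the windows of chromosome 2 had a median above 0.2. A change in the day 60 controls is argued against for chromosome 2, whose median was -0.0025 between the controls of day 60 and day 15, but in the controls themselves the region of chromosome 10 moved by 0.60, the value that this explanation needs there, while on chromosome 7 before 60 Mb the controls moved by -0.31 and TIM-KD at day 60 lay 0.29 above the day 15 controls, so both moved. Altered copy number in the TIM-KD cells, by outgrowth of a subclone, would show in both of their day 60 arrays, and 2 arrays had chromosome 2 high and chromosome 20 low. It stays open because no DNA was measured, and neither another origin of these cells nor an effect of the knockdown on chromosome segregation can be told from it.

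The third pattern is the fall of epithelial genes in TIM-KD cells at day 60. Their place on the shifted chromosomes is argued against by a median of -0.90 without those chromosomes, where 19 of 35 members fell (p = 7.33e-05 with an estimated correlation, limma). That speaks only to the place of the genes, and chromosome 11, with a day 60 median of -0.16, was kept in. A subclone or another origin of these cells, left open above, could also alter genes elsewhere and cannot be told apart here. Dilution by cells without epithelial genes would lower all members by a like factor. Of the members, 60.5% fell by less than 1 log2 or did not fall. This cannot decide, because no level limit was set and a member near background in the controls could not fall that far. Cells that lack only some of the members would also give uneven falls. The higher ZEB1 level is a hypothesis that has part of the values it needs: of the 25 members that fell, 80% were higher in ZEB1/TIM-KDs than in TIM-KD at day 15, but only 8 were called higher and the median was 0.43. The whole epithelial list, reported above, had a like median in that comparison, so these values do not set apart the members that fell. In ZEB1-KD against control 13 of these 25 were higher, with a median of 0.19, so the hypothesis needs a ZEB1 knockdown at day 60 to be tested.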

How the results depend on the processing

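With 2 arrays per group, the counts of genes depended on the fit, but no call of a named gene or list reversed its direction where it was run again: both with the replicate block, quantile normalization, dim probe sets left out and arrays left out, genes also within the time point, and lists also with centred arrays, an estimated correlation, fry and chromosomes left out. For called genes this says little. The group values of every called probe set did not overlap, so leaving out an array could not turn a sign. The replicate block, the fit within the time point and the dim filter leave the fold changes as they are. RMA had already quantile normalized the values. The settings were planned, except the crossed block, the chromosomes left out and quantile normalization for lists, which were chosen after the data were seen. The cause was not tested for any of the changes below, except that a 2-fold threshold on top of the same adjusted p can only lower a count. The order used below is TIM-KD, ZEB1-KD and ZEB1/TIM-KDs against control, ZEB1/TIM-KDs against ZEB1-KD and against TIM-KD, the interaction, TIM-KD at day 60, the difference of the 2 days, and time in the controls.

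Leaving out 1 array gave 1402 to 1790, 429 to 534, 531 to 958, 7 to 61, 683 to 870, 291 to 875, 938 to 988, 933 to 1523 and 2951 to 3449 genes, and 10 to 11, 4 to 6, 4 to 7, 3 to 6, 8 to 11, 8 to 10, 4 to 5, 11 to 15 and 15 to 17 lists. The correlation between comparisons ranged over 0.133 to 0.216 (TIM-KD with its effect in ZEB1-KD cells), 0.115 to 0.225 (TIM-KD at the 2 days) and 0.120 to 0.251 (ZEB1-KD with its effect in TIM-KD cells, 0.132 without TIM-KD day 15 replicate 2). Over genes called in the first comparison these were 0.448, 0.316 and 0.474. The lists that passed with an estimated correlation numbered 4, 0, 0, 0, 4, 3, 1, 4 and 8.

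Array groups carry the same replicate numbers, and with the replicate block the counts were 2075, 1092, 1003, 44, 892, 533, 1518, 1327 and 4166. With the replicate block within time point they were 718 for ZEB1-KD, 705 for ZEB1/TIM-KDs, 27 and 641 against the single knockdowns, 311 for the interaction and 1038 for the 2 days. Differences between replicates 1 and 2 correlated between groups by -0.54 to 0.17, the lowest between TIM-KD and ZEB1/TIM-KDs at day 15, so a shared number does not mark a shared batch there. With the TIM-KD day 15 numbers crossed the counts were 2619, 1683, 1570, 119, 1284, 959, 1994, 1898 and 5022.

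With only the groups compared in the fit, 1183 passed for TIM-KD, 303 for ZEB1/TIM-KDs, 8 and 103 against the single knockdowns, and 340 for the interaction. With only the arrays of the time point, 765 passed for ZEB1-KD, 746 for ZEB1/TIM-KDs, and 26 and 659 against the single knockdowns. A trend with a robust prior gave 276 for ZEB1/TIM-KDs against ZEB1-KD and 1450 for the interaction. Array weights gave 775 for ZEB1/TIM-KDs, 52 and 492 against the single knockdowns, 534 for the interaction and 2851 at day 60. Quantile normalization gave 122, and leaving out dim probe sets 130, for ZEB1/TIM-KDs against ZEB1-KD.

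A 2-fold threshold left 1260, 708 and 694 against control, 640 for ZEB1/TIM-KDs against TIM-KD, 1055 at day 60 and 2472 with time. An unadjusted p with 2-fold gave 1318, 773 and 757 against control, 205 and 719 against the single knockdowns, 1519 for the interaction, 1113 at day 60 and 2524 with time. Without chromosomes 2, 5, 7, 10 and 20 there were 1070 at day 60, 1104 genes and 10 lists for the 2 days, and 3696 with time.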

Other observations

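Genes outside the described groups also moved. In ZEB1-KD cells SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling, rose (1.76 ± 0.16 log2 ± SE, n = 2 per group), and PMEPA1, a TGF-beta target, fell (-2.24 ± 0.18). In the ERK output list, which did not pass, 8 of 29 rose and 5 fell (8 and 8 adjusted over the list alone, adjusted p = 0.0536). LAPTM5 (1.84 ± 0.24) and CD4 (1.64 ± 0.26), genes usually read as leukocyte markers, rose in ZEB1-KD, in a list in which 2 of 17 rose and 1 fell (2 and 1 adjusted over the list alone, adjusted p = 0.468).

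At day 60 RORA (3.88 ± 0.22), a nuclear receptor of the clock, rose in TIM-KD against control, and PPARGC1A (-3.07 ± 0.19), a coactivator of mitochondrial genes, fell. TNFRSF19 (3.47 ± 0.25) and DKK1 (at least 3.19 ± 0.24), both tied to Wnt signalling, rose, and CCND1, cyclin D1, fell (-2.93 ± 0.20). In the Wnt targets and intestinal stem cell list 7 of 25 rose and 3 fell (8 and 5 adjusted over the list alone, adjusted p = 0.360). The log2 level of ADAMTS19 had group means of 4.41 to 4.75 in 5 groups and 9.62 in TIM-KD at day 60.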
